A study of Salmo salar with 86 samples.

How the data were processed

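Scales of Atlantic salmon were cultured, exposed to bacteria or to medium and harvested, and total RNA was amplified and labelled with Cy3 for one-colour Agilent arrays, per the labels' protocols. Each of the 86 arrays carried 14841 probes. The authors deposited the scanner output of each array, made with Agilent Feature Extraction 12.0.1.1 and protocol GE1_1200_Jun14, per the file headers. The deposited processed intensity of a spot is background-subtracted and spatially detrended within the array, and is not normalized between arrays, per the file headers. The files also hold the median spot and background intensity, and other columns with marks for outlier, saturated and well-above-background spots, per the file headers. The authors also deposited 1 table of intensity values for all arrays. Set against the scanner values, that table held the median signal minus the median background, times 1 factor per array that brings the arrays of an experiment to nearly the same sum; its method is not given in the sources used here. 1 of its columns belonged to no sample and was not used. Genome build and aligner do not apply to these values.

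The main values were log2 of the processed signal minus the 75th percentile of the array. Spots marked as outliers were set missing, saturated spots were kept and control spots were left out. Each probe had 1 spot, so no spots were averaged. A probe was tested in an experiment if it was well above background on at least as many arrays as the smallest group held. Each experiment was fitted separately with limma 3.58.1 in R 4.3.3, with a term for each group and moderated variances, and probes were called at a Benjamini-Hochberg adjusted p under 0.05. The linear model was computed per pattern of missing values, which gave the same p-values as limma's own functions; for probiotic mix against Moritella, 2 probes whose other groups were wholly missing have no value in limma's functions and were kept here. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Where a probe was not above background on any array of a group, the fold was given as a bound. The dim group's value was the mean of, per array, the higher of the lowest signal well above background and the probe's own signal. The bound set this against the brighter group's mean and leaves out the error of that mean.

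The design, the tests and most alternatives were fixed before the data were examined. The array of NatBiom-1 Tenacibaculum culture 5 was not foreseen: it was left out after its quality values were seen and before any count of calls was made, under a limit of 50% marked spots that was chosen then. The planned rule for naming genes needed gene names. None of the 14841 identifiers, 13549 with the prefix Ssa and 1292 with the prefix Omy, matched the reference gene table, so 2 probes each way were named per comparison, those with the largest change among called probes for which every exposed array lay on 1 side of the control mean. Ssa#GRASP223648763 and Ssa#S30292942 are those of lowest p in the test among exposures. The planned gene lists and cell type markers could not be matched to probes and were not analysed here. The planned normexp setting needed a mean signal column; the median signal was used in its place, with an offset of 50.

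Simulated data had 200 changed probes, the spread of the real arrays and noise independent between probes. Shifts of many probes together are thus not in them. The fit was tested on these data. It recovered 72% of 2-fold and 99% of 4-fold changes in NatBiom-1 (Moritella against control, 12417 probes), 41% and 82% in NatBiom-2 (Pseudomonas, 11657 probes), 23% and 73% in AlgOil (full strength, 11869 probes) and 54% and 87% in BioAct (11925 probes), and called 0 probes where nothing was changed. The counts of calls therefore cannot be set against each other between experiments.

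Culture numbers are shared between groups in the titles. Whether they pair the arrays was checked by the correlation of deviations from group means between arrays of the same number, the numbers being taken to pair arrays where there were 3 or more pairs and every pair was over 0.1. This held for Moritella against control in NatBiom-1 (0.200 to 0.440), Tenacibaculum against control in NatBiom-1 (0.250 to 0.391) and BioAct (0.190 to 0.505), and for no other comparison by title numbers. In NatBiom-1 arrays of the same number always shared a slide and a row of it. Pairing by culture and by position thus cannot be told apart there. In BioAct they lay on different slides but shared the row. The sample descriptions of 2 NatBiom-2 arrays give other numbers than the titles: 6 for Pseudomonas culture 5 and 3 for Psychrobacter culture 4. By description numbers the rule also held for Psychrobacter against control (4 pairs, 0.140 to 0.256), where 1 pair was at -0.381 by title, and for no other NatBiom-2 comparison; with that number as a block Psychrobacter had 722 calls. By description most of the Psychrobacter pairs also shared a slide, so slide and culture cannot be told apart there either. Which number is right is not settled. Some blocked counts had been seen before these checks were made, and the check by description was added after the results; the rule was applied as written. Controls 63 and 64 of AlgOil correlated at 0.980, above all other pairs of that group (highest 0.969), with 0 identical values; they were kept as separate cultures, and averaged in an alternative. Cultures 1 and 1-13 of BioAct lay within the range of the other pairs.

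Alternatives were normexp, quantile normalization, the authors' table, no filter or a filter on every array, groups fitted alone or all arrays in 1 fit, array weights, trended and robust moderation, blocks for slide, scan day and culture number, and leaving out each culture. Correlations and overlaps between comparisons that share controls were set beside 100 simulations of unchanged groups and beside values with the controls split.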

Results

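Transcript levels were measured in cultures of Atlantic salmon scales, each culture being scales picked from the fish and kept in medium with the skin cells attached to them. The cultures were exposed to live bacteria or to medium alone for 2 h, washed, and harvested at 24 h. Total RNA of each culture was hybridised to 1 one-colour array, giving 86 arrays in 15 groups and 4 experiments named NatBiom-1, NatBiom-2, AlgOil and BioAct, each with its own controls. NatBiom-1 held 6 cultures each of control, Moritella viscosa, Tenacibaculum finnmarkense and a mixture of probiotic bacteria. NatBiom-2 held 5 cultures each of control, Aliivibrio, Pseudomonas, Psychrobacter and a mixture of bacteria. AlgOil held 7 controls and Moritella viscosa at full strength (4 cultures), diluted 1:10 (7) and diluted 1:100 (7). BioAct held 6 controls and 6 cultures with Tenacibaculum finnmarkense. One array, culture 5 of the NatBiom-1 Tenacibaculum group, had 85.8% of its spots marked as outliers by the scanner software and was left out, leaving 85 arrays. On the arrays used the median share of probes well above background was 81.1% in NatBiom-1, 77.7% in NatBiom-2, 73.7% in AlgOil and 81.4% in BioAct. The lowest shares were 48.3%, in AlgOil, and 49.1%, on the array of NatBiom-2 mixture culture 4. The number of arrays limits the precision: the median SD between cultures of a group was 0.35 in NatBiom-1, 0.39 in BioAct, 0.49 in NatBiom-2 and 0.61 in AlgOil on the log2 scale. The labels call the cultures separate, and nothing says that they came from separate fish, so p-values measure the spread between cultures. Probes are given by their identifiers on the array, because the files used here do not pair them with gene names.

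Moritella viscosa and Tenacibaculum finnmarkense in NatBiom-1 were compared with medium to ask what each bacterium changed in the scale cultures. After Moritella, Ssa#S31963958 rose from -6.51 ± 0.98 to -1.90 ± 0.52 (mean ± SD of log2 signal relative to the array, n = 6 and 6), a log2 change of 4.60 ± 0.39 (SE), and Ssa#S41489473 rose by 4.03 ± 0.36 or 16.4-fold. Ssa#S31963958 was well above background on only 3 of the 6 controls, so its measured change here and with the other NatBiom-1 exposures rests in part on control signals within background. Ssa#S35569016 fell by 3.03 ± 0.52 (SE) and was well above background on 5 of the 6 controls and on 0 of the 6 exposed arrays, a fall of at least 2.27-fold. Ssa#S35703775 fell by 3.87 ± 0.79, from controls that were widely spread (SD 2.23) and of which 5 of 6 were above background, to exposed arrays of which 1 of 6 was. In all, 2080 of 12650 probes differed from control by limma at an adjusted p under 0.05, 914 higher and 1166 lower, and 507 of them by more than 2-fold. The split between higher and lower calls depended on the scaling: it was 742 higher and 558 lower after normexp background correction, 862 and 714 after quantile normalization, and 603 and 3356 in the authors' deposited table, so no overall direction is given.

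After Tenacibaculum, Ssa#DW182251 rose by 4.10 ± 0.27 (SE; adjusted p 3.88e-09 by limma). It was well above background on 5 of 5 exposed arrays and on 0 of 6 controls, so the rise was at least 5.09-fold. Ssa#S31963958 rose by 3.77 ± 0.41. Ssa#S35703775 fell at least 5.12-fold and Ssa#S31999264 at least 1.85-fold (measured changes -3.95 ± 0.82 and -2.29 ± 0.51), as neither was above background on any of the 5 exposed arrays. The count was 1125 of 12650 probes, 581 higher and 544 lower, and 292 by more than 2-fold. Here the split was 461 higher and 272 lower after normexp, and 444 and 1307 in the authors' deposited table. Leaving out culture 4 of the group gave 583 calls, culture 1 gave 694, and control 2 gave 724; with the array of culture 5 and all its spots in the fit the count was 154.

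Both bacteria raised many of the same probes: 466 were higher and 401 lower in both comparisons, and 0 went opposite ways, where independent lists of these lengths share 42.0 and 50.2. The comparisons use the same controls. Unchanged groups simulated against those controls shared a mean of 0.240 and at most 19 calls, but such groups have few calls to share, so that count does not judge the overlap. They gave a correlation of changes of 0.469, beside 0.806 observed across probes. The covariance of the changes was 0.185, and 0.0371 in the simulation. With the controls split between the comparisons the correlation was 0.554, and a mean of 190 probes were higher and 81.8 lower in both. Compared directly with Moritella, Tenacibaculum cultures had 7 probes higher and 0 lower. Of these Ssa#DW182251 was higher by 4.20 ± 0.27, at least 5.46-fold, and Ssa#TC96050, above background on 2 of 6 Moritella arrays, by 2.01 ± 0.38 (adjusted p 0.0447 by limma). That count ranged from 1 without Moritella culture 1 to 8 without Tenacibaculum culture 3, and was 0 after normexp.

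The probiotic mixture in NatBiom-1 was compared with medium in the same way. Ssa#S31963958 rose by 6.42 ± 0.39 (SE, n = 6 and 6), to -0.09 ± 0.59 (SD), and Ssa#S41489473 by 5.99 ± 0.36 or 63.5-fold. Ssa#CB509890 fell by 4.99 ± 0.81 and Ssa#S18866399 fell by 4.92 ± 0.61, the controls of the first having an SD of 2.31; they were above background on 3 and 4 of the 6 exposed arrays. The count was 3176 of 12649 probes, 1591 higher and 1585 lower, and 1175 by more than 2-fold; in the authors' deposited table the split was 1051 and 2873. The sample descriptions carry a code for this group that may name Moritella as well, so whether Moritella was also present is not settled.

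The probiotic mixture was also compared directly with Moritella. Ssa#DW577519 was higher by 3.98 ± 0.54 (SE, n = 6 and 6) and Ssa#TC96050, above background on 2 of 6 Moritella arrays, by 3.32 ± 0.36, while Ssa#S18866399 was lower, at -4.34 ± 0.61, and Ssa#CB509890 was lower, at -3.94 ± 0.81. The count was 2177 of 12649, 1414 higher and 763 lower. After quantile normalization it was 766 higher and 835 lower, so the excess of higher calls depended on the scaling. Without probiotic culture 1 the count was 1289, without Moritella culture 1 it was 1375 and without Moritella culture 6 it was 1432.

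In NatBiom-2 the question was what single genera and a mixture of bacteria changed. The same 2 probes led every comparison. Ssa#S31963958 stood at -6.96 ± 1.35 (SD, n = 5) in controls, of which only 2 of 5 were above background, and rose by 5.44 ± 0.43 (SE) with Aliivibrio, 6.00 ± 0.43 with Psychrobacter, 6.72 ± 0.43 with the mixture and 7.09 ± 0.43 with Pseudomonas. Ssa#S41489473 stood at -3.47 ± 0.48 in controls and rose by 4.99 ± 0.29 with Aliivibrio, 5.06 ± 0.29 with Psychrobacter, 6.20 ± 0.29 with Pseudomonas and 6.46 ± 0.29 with the mixture.

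**Figure D1:**
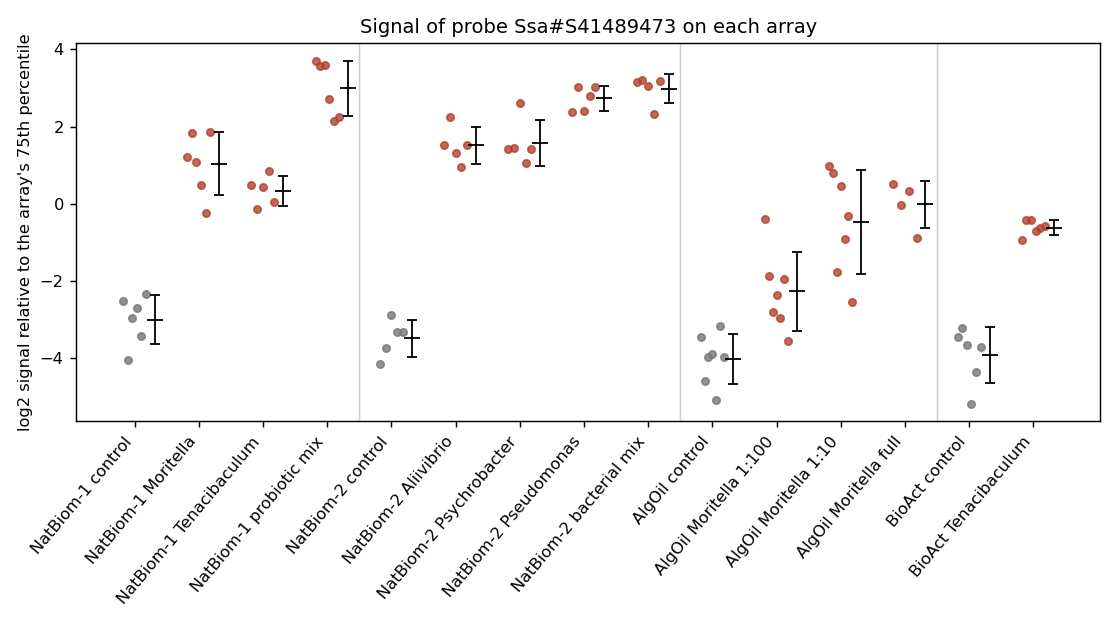
Log2 signal of probe Ssa#S41489473 relative to the 75th percentile of its array (vertical axis) on each array of the 15 groups (horizontal axis), grey for controls and red for exposed cultures. Black bars are the mean ± SD; the group means of NatBiom-2 run from -3.47 in controls to 2.98 with the mixture.

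Among the probes that fell, Ssa#GRASP209155213 fell by 3.46 ± 0.30 (SE) and Ssa#S30270374, above background on 1 of 5 exposed arrays, fell by 2.99 ± 0.54 with Aliivibrio. With Psychrobacter Ssa#S35703775 fell by 4.26 ± 0.75, at least 5.03-fold since it was above background on 0 of 5 exposed arrays, and Ssa#S35685886, above background on 2 of 5, fell by 3.48 ± 0.72. With the mixture Ssa#S35569016 fell by 4.11 ± 0.60, at least 4.34-fold, and Ssa#GRASP209156159, above background on 3 of 5, fell by 3.73 ± 0.37. With Pseudomonas Ssa#TC109014 fell at least 10.7-fold (measured change -4.67 ± 1.43, adjusted p 0.0308 by limma) and Ssa#S31963372 at least 6.06-fold (-4.58 ± 1.36). Both were above background on 0 of 5 exposed arrays and had widely spread controls (SD 2.64 and 2.47). The bounds take the control mean as exact, so for these 2 probes the true fall may be smaller.

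The mixture gave 2054 calls of 12316 probes (1008 higher, 1046 lower), Pseudomonas 1648 (795 and 853), Aliivibrio 645 of 12315 (360 and 285) and Psychrobacter 634 (403 and 231). After normexp the counts were 805 (486 and 319), 622 (411 and 211), 188 (146 and 42) and 237 (192 and 45). In the authors' deposited table the splits were 570 and 1865 for the mixture, 550 and 1259 for Pseudomonas, and 260 and 362 for Aliivibrio. Without 1 array the Aliivibrio count fell to 368 (culture 1), 373 (control 4) or 402 (culture 5), and the Psychrobacter count to 377 (control 4), 396 (culture 4) or 414 (culture 1). Aliivibrio, Pseudomonas and Psychrobacter had arrays on slide 4, which held no controls or mixture arrays and was alone on its scan day. With slide as a block their counts were 837, 1521 and 577, and a test among the 4 exposures, given next, called 41.

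The 4 exposures were then compared with each other. A test of any difference among them called 42 of 12315 probes, and Pseudomonas was the highest of the 4 in 23 of these and Aliivibrio the lowest in 23. Ssa#GRASP223648763 rose by 4.75 ± 0.24 (SE) with Pseudomonas, 4.19 ± 0.24 with the mixture, 3.22 ± 0.24 with Psychrobacter and 2.65 ± 0.24 with Aliivibrio (adjusted p of the difference 0.000378 by limma). Ssa#S30292942 rose by 2.30 ± 0.29 with the mixture and 2.03 ± 0.29 with Pseudomonas, and its changes with Psychrobacter (0.64 ± 0.29) and Aliivibrio (0.12 ± 0.29) did not pass the test. The count was 5 after normexp and ranged from 20 without Pseudomonas culture 5 to 59 without Psychrobacter culture 4.

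Pairs of NatBiom-2 comparisons shared many calls. Pseudomonas and the mixture shared 598 higher and 583 lower probes, where independent lists share 65.1 and 72.4, and Aliivibrio and Psychrobacter shared 308 and 151, where independent lists share 11.8 and 5.35. Aliivibrio and Psychrobacter both had arrays on slide 4, which held no controls. The simulation shuffled arrays over slides, so an effect of that slide is not in it. Unchanged groups simulated against the same controls shared at most 1 and 0 calls in these 2 pairs, but have few calls to share, so these counts do not judge the overlap. The simulated correlations of changes were 0.507 and 0.503 beside 0.828 and 0.889 observed, and with the controls split between comparisons the observed values were 0.627 and 0.596. The covariances were 0.412 and 0.298, beside 0.0793 and 0.0783 in the simulation.

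AlgOil tested Moritella viscosa at 3 doses. At full strength Ssa#S41489475 rose from -4.66 ± 0.39 (SD, n = 7) to -0.59 ± 0.77 (n = 4), by 4.07 ± 0.65 (SE), and Ssa#S41489473 by 4.00 ± 0.59, with 4 and 6 of the 7 controls above background. At 1:10 (n = 7) they rose by 3.49 ± 0.55 and 3.54 ± 0.51. The full-strength count was 21 of 12086 probes and the 1:10 count 13, all higher, and 11 probes were called at both doses, where independent lists share 0.0226. The doses share their controls: the correlation of changes was 0.536, beside 0.423 for simulated unchanged groups, and the covariance 0.119 beside 0.102. With the controls split between the doses the correlation was -0.02, and a mean of 0.5 probes were called at both. At 1:100 limma called 0 probes, with 488 at an unadjusted p under 0.05, and between full strength and 1:100 it called 0, with 937 at an unadjusted p under 0.05. These counts were small and moved easily: full strength had 7 calls without culture 3, 8 without culture 5, 13 without control 3 and 10 when compared alone with controls, and 1:10 had 5 without culture 1 or culture 1-1. Full strength also had 6 calls in the authors' table, 12 with scan day as a block and 0 with culture number as a block, though numbers did not pair these arrays. Full strength against 1:100 had 6 calls without 1:100 culture 2, 12 without both that culture and culture 1 of 1:10, 3 with slide as a block and 84 with all experiments in 1 fit, in which 1:100 had 30 against control. Neither full-strength nor 1:100 cultures shared a slide with controls. Slide and dose can be told apart against controls at these 2 doses only indirectly, through culture 1 of 1:10 on slide 1, and this bears on the 0 calls at 1:100 too. With slide as a random block, which corrects for slides only in part, full strength had 18 calls and 1:100 had 0. At 1:10, with slide as a block, the count was 10. The 13 probes were higher on each of the 3 slides that held both groups, but they were chosen on these same arrays.

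BioAct compared Tenacibaculum finnmarkense with medium in another set of cultures. Ssa#S18836090 rose from -2.44 ± 0.76 to 1.21 ± 0.43 (SD, n = 6 and 6), by 3.64 ± 0.33 (SE) or 12.5-fold. Ssa#S31963958 rose at least 3.21-fold, as 0 of 6 controls were above background (measured change 3.41 ± 0.35). Ssa#CL241Contig1 fell by 5.52 ± 0.93 and Ssa#CL4Contig1 fell by 5.26 ± 1.03, with SDs of 2.20 and 2.48 among the controls; they were above background on 1 and 2 of the 6 exposed arrays. The count was 121 of 12075 probes, 99 higher and 22 lower. Culture numbers paired the arrays here, and with the pairs as a block the count was 220 (161 higher, 59 lower). With slide as a block it was 69 (66 higher, 3 lower), so few of the falls were called there. Without culture 5 it was 78 (70 higher, 8 lower). The 121 probes had the same sign within each of the 3 slides, but they were chosen on these same arrays, and 2 of the slides held only 1 array of a group.

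**Figure D2:**
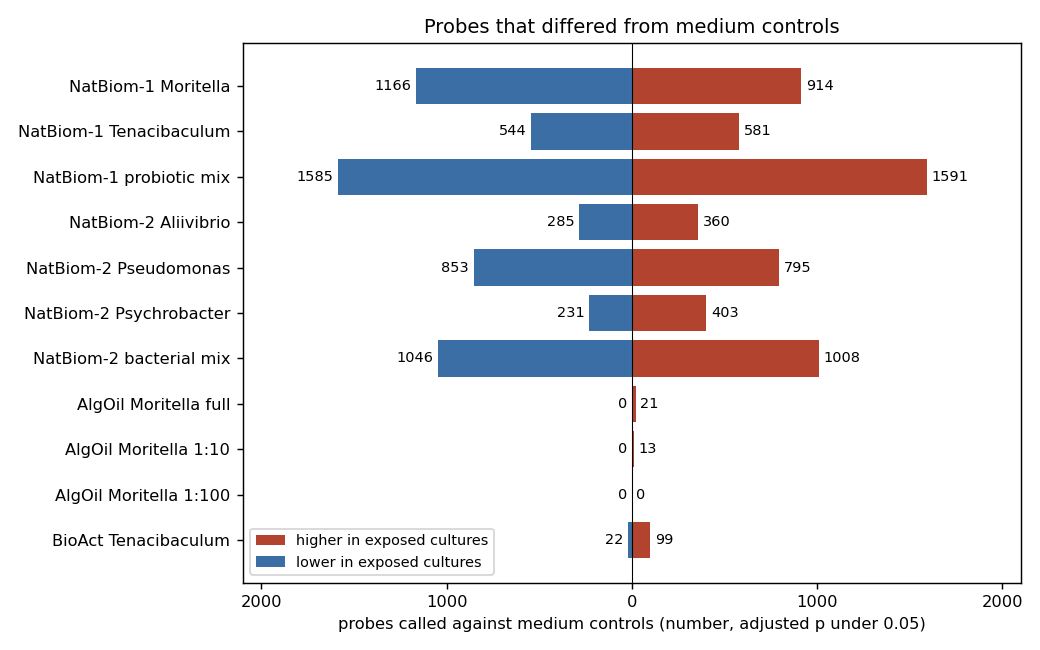
Number of probes called higher (red, to the right of 0) or lower (blue, to the left) than medium controls at an adjusted p under 0.05, for the 11 exposures on the vertical axis. The counts run from 0 at AlgOil 1:100 to 1591 higher and 1585 lower with the NatBiom-1 probiotic mixture.

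The 2 bacteria used in more than 1 experiment allowed the changes to be compared between experiments. For Tenacibaculum, NatBiom-1 and BioAct shared 80 higher and 7 lower calls, where independent lists share 4.65 and 0.822. Across 12017 probes, which are not independent replicates, Pearson's r of the changes was 0.365 (jackknife SE over arrays 0.140) and Spearman's rho 0.275. A test of the difference between experiments called 1 of 12017 probes: Ssa#S35538602 differed by 1.51 ± 0.25 (SE; adjusted p 0.0402 by limma). It stood at 1.81 ± 0.22 (SD, n = 5) against -0.26 ± 0.39 (n = 6) in NatBiom-1 and at 0.40 ± 0.19 against -0.16 ± 0.29 (n = 6 and 6) in BioAct. The difference was not called with slide as a block or without any 1 of 14 arrays. Culture numbers paired the arrays in both experiments, but this test was not run with the pairs as a block. The agreement between NatBiom-1 and BioAct was not particular to Tenacibaculum. NatBiom-1 Moritella shared 87 higher and 10 lower calls with BioAct (r 0.528). For the NatBiom-2 exposures r with BioAct was 0.562 (Psychrobacter), 0.504 (Aliivibrio), 0.482 (Pseudomonas) and 0.378 (the mixture). It was 0.310 for the NatBiom-1 probiotic mixture and at most 0.264 in AlgOil.

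For Moritella, NatBiom-1 and AlgOil at full strength shared 19 higher calls, out of 21 in AlgOil, where independent lists share 1.58. Other NatBiom exposures shared from 18 (Aliivibrio, Psychrobacter) to 20 (Pseudomonas, the probiotic mixture) with AlgOil full strength, and BioAct shared 10. The labels give no dilution for NatBiom-1, so its Moritella dose is not known to match that of AlgOil. For Moritella, Pearson's r across 11884 probes was 0.216 (jackknife SE 0.184) and Spearman's rho 0.0799. After normexp they were 0.0855 and -0.109. For the other NatBiom exposures r with AlgOil full strength ran from 0.210 (Psychrobacter) to 0.407 (the NatBiom-2 mixture), and for BioAct it was -0.034. The agreement was thus not particular to Moritella. The test of the difference called 1 of 11885 probes: Omy#S34309198 differed by -1.83 ± 0.30 (adjusted p 0.0494 by limma). It stood at -3.65 ± 0.29 (SD, n = 6) against -2.11 ± 0.37 (n = 6) in NatBiom-1, and at -3.68 ± 0.25 (n = 4) against -3.97 ± 0.39 (n = 7) in AlgOil. The count ranged from 0 to 85, the latter without AlgOil full-strength culture 4. Omy#S34309198 was not called after quantile normalization, with no filter, with array weights or with trended and robust moderation. With a filter on every array it was not among the 2 calls. With scan day as a block the 1 call was another probe, with a difference of the opposite sign.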

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

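All tests of explanations in this part were chosen only after the result they bear on was seen, and the same holds for the bounds they are read against. The splits of the arrays were planned, and their counts had been seen before the bounds for reading them were written down. Among 102 groups of values examined, 8 held a value far from the others, and chance gives about 5.1.

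The array of NatBiom-1 Tenacibaculum culture 5 had 85.8% of its spots marked, where the other arrays of the group had at most 0.391%, and 100.0% of its probes counted as well above background, where the others had at most 83.0%. Its 77 negative-control spots, which are not meant to bind sample RNA, had a median raw signal of 51. This lay above the other NatBiom-1 arrays (17 to 20) but below 1 AlgOil array (82). Of them 9.09% were marked, where other arrays had up to 11.7%, so these spots alone do not decide whether hybridisation or scan failed. The 75th percentile of its signal was 4738, where the other NatBiom-1 arrays had at most 407. With marked spots included, its mean correlation with its experiment was 0.379, where the others had at least 0.933. Both values go with a failed hybridisation or scan, which was not tested on them and stays open. Over 224 called probes unmarked on this array, its differences from controls correlated at only 0.315 with the change on the other 5 arrays. Those reached at least 0.900 each against the rest. A failed array would correlate poorly whether or not its culture responded, so nothing follows for the culture of this array. Ssa#DW182251 stood at -4.08 on it, near the other Tenacibaculum arrays (-4.10 to -2.72), but 48 unmarked probes as dim as it in controls had a median of -4.57 there, so its level does not settle the label. Over 1915 unmarked probes its highest correlation with another array, a NatBiom-2 mixture array, was 0.949, above the bound set for a wrong label (0.904), but 2 other NatBiom-1 arrays can correlate as low as 0.947 over the same probes, so the test identifies no other group, and a wrong label, which would not account for the marked spots, stays open.

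In AlgOil the titles number culture 1 of the 1:10 group and culture 2 of the 1:100 group in a run with the full-strength cultures, and the fit without both was planned for that reason. Over 67 probes that were higher in all 8 exposures of the other experiments, culture 1 had a mean change of 2.18, where the other 1:10 cultures had 0.68 to 1.51, and culture 2 had 1.40, where the other 1:100 cultures had -0.15 to 0.60. Culture 2 was alone in its group in lying above the lowest full-strength culture (1.02), which a wrong label could give; culture 1 lay above the highest (1.89), but 4 other 1:10 cultures also lay above the lowest, so for culture 1 the test decides nothing. Culture 2 lay 3.01 SD of the other 1:100 cultures above the higher of the other 1:100 cultures on its slide, which argues against slide 1 as its whole cause. The 1:100 cultures of slide 1 (1.40, 0.60 and 0.288) all lay above those of slides 2 and 3 (-0.15 to 0.286), and culture 1 was also on slide 1. A part played by slide 1 thus stays open for culture 2, and for culture 1 the slide stays open. The design gives no biological explanation for single cultures, and none was tested; culture to culture variation stays open too.

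Moritella gave 21 calls in AlgOil at full strength and 2080 in NatBiom-1. Probes were chosen on part of the NatBiom-1 arrays in 20 random ways, of which the 18 that gave 20 probes or more were used. The medians below thus leave out the choices with the fewest probes. The change on the held-out NatBiom-1 arrays had a median slope of 0.809 on the change used for choosing. The AlgOil full-strength change had a slope of 0.509 (jackknife SE 0.0845) over the same probes, which argues against fewer and noisier arrays as the whole cause, though the error of the held-out slope is not in that SE. With the NatBiom-1 changes of called probes added to shuffled AlgOil arrays, a median of 360.5 probes were called (94 to 1243 in 100 simulations). Fewer and noisier arrays thus lowered the count by much. The changes added were those measured on called probes, which tend to be too large. Full-strength cultures and controls shared no slide, so the full-strength slope does not part slide from dose. With slide as a random block, which corrects for slides only in part, full strength had 18 calls. Compared within slides, the 1:10 cultures had slopes of 0.237 to 0.444 over 485 probes chosen on all NatBiom-1 arrays, at a lower dose. A smaller response in these cultures, or a weaker dose, may underlie the difference and was not tested.

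Other values far from their group were as follows. Ssa#S35703775 was -5.19 in NatBiom-1 Moritella culture 4, where the other cultures lay between -8.48 and -7.41. Ssa#S41489473 was 2.60 in NatBiom-2 Psychrobacter culture 4 (others 1.04 to 1.44) and 2.33 in NatBiom-2 mixture culture 5 (others 3.04 to 3.22). The share of marked spots was 0.330% on the array of NatBiom-2 mixture culture 5, 0.586% on that of AlgOil 1:100 culture 2-1 and 0.546% on that of BioAct Tenacibaculum culture 2. The effect of Tenacibaculum on Ssa#S35538602 differed between NatBiom-1 and BioAct by 1.51, and the effect of Moritella on Omy#S34309198 differed between NatBiom-1 and AlgOil by -1.83, by limma's test of the difference.

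Other splits of the same arrays were fitted, 100 for each comparison with the real split among them. In NatBiom-1 only 1 of 100 splits, the real one, gave as many calls for Moritella (2080, highest other split 563), Tenacibaculum (1125 and 784), the probiotic mixture (3176 and 1534), the mixture against Moritella (2177 and 821) and Tenacibaculum against Moritella (7 and 0). The same 1 of 100 held for Aliivibrio (645 and 305), Pseudomonas (1648 and 205), Psychrobacter (634 and 73), the NatBiom-2 mixture (2054 and 480), the test among the 4 exposures (42 and 16) and BioAct (121 and 50). This argues against a chance split for each of these counts taken alone, with no adjustment over the comparisons. Where culture numbers of the titles pair the arrays, the real split was also the largest of the splits that part every pair: 1 of 32 for Moritella (highest other 556), 1 of 16 for Tenacibaculum (0) and 1 of 32 for BioAct (1). With only 16 such splits the check for Tenacibaculum cannot reach a share under 0.05, so it decides nothing alone. For AlgOil full strength, 4 of 100 splits gave as many as the 21 calls and 1 gave 1051, many times the real count, which points to a structure of the samples that the groups do not follow; it put cultures of slides 2, 3, 4 and 6 together. For 1:10, 2 of 100 splits gave 13 or more (highest other 13). For 1:100 and for full strength against 1:100 the real count was 0, so 100 of 100 splits gave as many (highest others 1 and 130). The split with 130 calls put 4 arrays of slide 3 together, and with slide as a block the count for full strength against 1:100 was 3. For the differences between experiments, 4 of 100 gave as many as 1 call for Tenacibaculum (highest other 2), and 9 of 100 for Moritella (highest other 247), so chance is not excluded for the latter. The Tenacibaculum difference rests on 1 call, which was lost with slide as a block, so chance is not excluded for it either.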

How the results depend on the processing

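The fits with the array of NatBiom-1 Tenacibaculum culture 5 were chosen only after its quality was seen; the other alternatives were planned. Of 975 values of named probes under alternatives, 921 kept direction and call, 54 kept direction but were not called and 0 reversed; Ssa#TC96050 against Moritella lost its call in 16, and Ssa#CL4Contig1 in BioAct and Ssa#TC109014 with Pseudomonas in 8 each. The counts below moved by over 1.5 times, apart from those in the last paragraph, which gives the full range of leaving out each culture; the cause was not tested unless stated. Probes not above background on any array of a group have only a bound there. The planned gene lists were not run. Scaling also moved the median change of all probes, by -0.18 for NatBiom-1 Moritella and the probiotic mixture, -0.14 for Tenacibaculum and -0.21 for the NatBiom-2 mixture in the authors' table, by 0.21 for Aliivibrio, 0.17 for Pseudomonas, 0.30 for the NatBiom-2 mixture, 0.16 for AlgOil full strength, 0.14 for 1:10 and 0.19 for 1:100 with normexp, and by -0.12 for the probiotic mixture against Moritella with quantile normalization.

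With normexp the counts were 1300 for NatBiom-1 Moritella, 733 for Tenacibaculum, 0 for Tenacibaculum against Moritella, 188 for Aliivibrio, 622 for Pseudomonas, 237 for Psychrobacter, 805 for the NatBiom-2 mixture, 5 among the exposures, 5 for the Tenacibaculum difference and 15 for the Moritella difference, and the correlation of changes was 0.524 for Tenacibaculum and 0.0855 for Moritella, where rho turned to -0.109 and 35.3% of probes had the same sign (50.7% without normexp). With quantile normalization they were 4 for Tenacibaculum against Moritella, 2 for the Tenacibaculum difference and 0 for the Moritella difference. In the authors' table they were 3959 for NatBiom-1 Moritella, 1751 for Tenacibaculum, 6 for AlgOil full strength, 17 among the exposures, and 0 and 84 for the Tenacibaculum and Moritella differences. With a filter on every array they were 2 for Tenacibaculum against Moritella, 4 for the Tenacibaculum and 2 for the Moritella difference, and with no filter 2 and 0 for those differences. Over probes called in either experiment the correlations were 0.701 for Tenacibaculum and 0.532 for Moritella, on probes chosen for their change.

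With all arrays in 1 fit, where noisier experiments share the spread, the counts were 802 for NatBiom-1 Moritella, 399 for Tenacibaculum, 1898 for the probiotic mixture, 615 for that against Moritella, 1 for Tenacibaculum against Moritella, 157, 74 and 30 for AlgOil full strength, 1:10 and 1:100, 84 for full strength against 1:100 and 39 for the Moritella difference. With only the groups compared they were 642 for NatBiom-1 Tenacibaculum, 1 for that against Moritella, 349 for Aliivibrio, 1297 for the NatBiom-2 mixture and 10 for AlgOil full strength, with fewer arrays. Array weights gave 1709 for NatBiom-1 Tenacibaculum, 27 for that against Moritella, 1205 for Aliivibrio, 2941 for Pseudomonas, 1367 for Psychrobacter, 8 for AlgOil 1:10, 125 among the exposures, and 6 and 0 for the Tenacibaculum and Moritella differences. Trended and robust moderation gave 21 for AlgOil 1:10 and 0 for the Moritella difference.

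With slide as a block the counts were 3 for full strength against 1:100, 69 for BioAct and 0 for the Tenacibaculum difference, and with scan day 12 for AlgOil full strength. With a replicate block by culture number they were 220 for BioAct, where numbers pair the arrays; where they do not, 11 for Tenacibaculum against Moritella, 0 for AlgOil full strength and 22 among the exposures. The block moved no other count by over 1.5 times where it was fitted. It was not fitted for AlgOil 1:10, 1:100, full strength against 1:100 or the differences between experiments. With controls 63 and 64 averaged AlgOil 1:10 had 6 calls. Without culture 1 of 1:10 and culture 2 of 1:100, full strength had 32 and full strength against 1:100 had 12. With culture 5 of NatBiom-1 Tenacibaculum and all its spots, the counts were 296 for Moritella, 154 for Tenacibaculum, 1132 for the probiotic mixture, 251 for that against Moritella and 0 for the Tenacibaculum difference; with its marked spots missing only that difference moved, to 0.

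Leaving out 1 culture at a time gave 1391 to 2284 for NatBiom-1 Moritella, 583 to 1406 for Tenacibaculum, 2705 to 3281 for the probiotic mixture, 1289 to 2431 for that against Moritella and 1 to 8 for Tenacibaculum against Moritella. In NatBiom-2 it gave 368 to 890 for Aliivibrio, 1220 to 1565 for Pseudomonas, 377 to 791 for Psychrobacter, 1473 to 2231 for the mixture and 20 to 59 among the exposures. In AlgOil it gave 7 to 23 at full strength, 5 to 20 at 1:10, 0 at 1:100 and 0 to 6 between full strength and 1:100, in BioAct 78 to 131, and 0 to 2 and 0 to 85 for the Tenacibaculum and Moritella differences. Leaving out 1 culture moved no count by over 1.5 times for NatBiom-1 Moritella, the probiotic mixture, Pseudomonas, the NatBiom-2 mixture and 1:100. The correlations of changes ran from 0.305 to 0.440 for Tenacibaculum and from 0.118 to 0.314 for Moritella.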

Other observations

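All tests in this part were chosen only after the results were seen.

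A set of probes rose in every exposure of 3 experiments. Of 11703 probes tested in NatBiom-1, NatBiom-2 and BioAct, 68 were called higher in all 8 exposures and 4 were called lower, where 3 lists, each of the probes called that way in every exposure of 1 experiment, would share 0.0718 and 0.00449 if independent of each other. Overlap within an experiment, where exposures share controls, is already inside those lists; between experiments the controls were separate. In AlgOil, whose arrays took no part in choosing them, 67 of the 68 probes were tested. Their median log2 change was 1.31 at full strength (66 positive), 1.07 at 1:10 (65 positive) and 0.36 at 1:100 (58 positive).

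The mean change of these probes on each AlgOil array was tested against controls by an exact two-sided permutation test, adjusted over the 3 doses. It was 1.42 higher at full strength (n = 4 and 7, exact p 0.00303, the smallest these arrays can give; adjusted 0.00455), 1.23 at 1:10 (n = 7 and 7, exact p 0.000583, also the smallest; adjusted 0.00175) and 0.37 at 1:100 (n = 7 and 7, exact p 0.111, adjusted 0.111), so a rise at 1:100 was neither shown nor excluded. Full-strength and 1:100 cultures shared no slide with controls, so for these 2 doses slide and dose cannot be told apart in this test. Without culture 1 the difference at 1:10 was 1.07 (exact p 0.00117), and without culture 2 it was 0.20 at 1:100 (exact p 0.220). Within slides 2 and 3, which held full-strength and 1:100 cultures, full strength was higher by 1.34 ± 0.30 (SE), with each of its 4 cultures above every 1:100 culture of its slide, which argues against slides as the source of that difference; the exact p of 0.0556 is the smallest that these 36 arrangements allow. Within slides 4 to 6 the 1:10 cultures were higher than controls by 1.06, and 6 of 6 lay above every control of their slide. A response common to many bacteria is a hypothesis that was not tested. AlgOil does not bear on it, since it used Moritella, which was among the exposures used for choosing the probes. A trend with dose was not tested either.

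Ssa#DW182251, the probe with the lowest p after Tenacibaculum in NatBiom-1, was singled out after its values were seen. It was well above background on 0 of the 74 arrays without Tenacibaculum. In BioAct it was too dim for the planned filter, and was well above background on 4 of 6 exposed arrays and 0 of 6 controls (Fisher's exact p 0.0606, two-sided). The measured values were -5.60 ± 0.43 (SD) with Tenacibaculum and -7.38 ± 0.95 in controls, a difference of 1.78 (exact two-sided permutation p 0.00649). That difference rests on control signals within background. With values below background set to the lowest signal well above background on their array, the difference was 0.25 (n = 6 and 6, exact two-sided permutation p 0.152). BioAct thus neither shows nor excludes a rise. Whether it reads a salmon transcript or bacterial RNA left in the wells was not tested.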
